A study of Mus musculus with 8 samples.

How the data were processed

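Total RNA from hepatic macrophages of FVB/N mice with acetaminophen injury was measured on 8 Affymetrix arrays, 4 from mice given recombinant transferrin and 4 from mice given recombinant CPS1. RNA was extracted with Qiagen RNeasy and biotinylated cDNA was made from 400 ng of it with the WT Plus kit, per the labels' protocols. The values are log2 expression levels deposited by the authors, which were made with RMA (background correction, quantile normalization and summary of probes), per the submitters' processing notes, which name limma as well and give no versions. Because RMA forces the arrays to a common distribution, a shift shared by nearly all genes would not be visible. How the macrophages were isolated, the time between acetaminophen and isolation, the genome build of the array design and its probe filters were not given in the sources used here, so no coordinates are printed. Samples were grouped by their titles, which also gave the replicate numbers, and no pair of arrays held the same values.

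The table held 41345 rows, of which 23521 had exactly 1 gene symbol in the platform annotation, 1814 had several and 16010 had none. Rows with several symbols or none were left out of the gene tests. By Entrez ID 23328 rows matched the NCBI RefSeq gene table (assembly GRCm38.p6, used for names only), which changed 0 symbols. For the 1082 genes with more than 1 row the row of highest mean over the 8 arrays was used, giving 22180 genes, with no filter on dim rows. Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, two-sided, no covariate) and Benjamini-Hochberg adjustment at 0.05. Before the data were examined, 30 gene lists for activation states, liver and blood cell types and pathways of acetaminophen injury were written down. They hold 646 different genes, of which 584 were measured and 24 lay only on rows with several symbols. Each list was tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 30 lists, with the correlation estimated from the residuals and with fry as alternatives. At the preset correlation 8 lists passed. With an estimated correlation 1 list passed, the monocyte list, and 1 passed in fry's directional test. Estimating the correlation also sets camera's statistic against the 6 residual degrees of freedom, so a call lost there may not be due to correlation alone. In fry's mixed test, which asks whether a list's genes change either way, 2 passed. Each list's mean log2 level per array was compared by a two-sided exact permutation test over all 70 assignments, whose smallest p is 0.0286.

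The genes named follow a rule set in advance: the 12 of largest change in each direction past the threshold with groups that do not overlap or, failing that, the 12 of smallest p in each direction, leaving out predicted genes, clones, microRNA and small nucleolar RNA genes and chemosensory receptors. The rule added up to 4 members of smallest p in a list's direction for each list that passed, up to 2 members of each other list, and 20 genes fixed in advance for the injected proteins and for macrophage activation and origin. Genes outside the rule are said to be chosen after their values were seen.

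The gene and list tests were tested on simulated data with the means and spread of these 22180 genes. Of 50 genes changed at each size, 8% were recovered at a log2 change of 0.5, 70% at 1, 90% at 1.5 and 94% at 2, with 8 false calls. A list shifted by -0.5 was called in 20 of 20 simulated data sets and 0 other lists were. The simulated genes varied independently, whereas members of the T and NK cell list, for example, had an estimated correlation of 0.58 on these arrays. The simulation therefore does not give the rate of false list calls here. Of the 35 splits of the 8 arrays into 4 and 4, 26, the real one among them, called at least 8 lists. Alternatives were a filter on rows below the median level, trended and robust variance, array weights (with statmod 1.5.0 installed), the replicate number as a block, quantile normalization of the deposited values, the mean of all rows of a gene, the hepatocyte list mean as a covariate, all array rows, each array left out in turn, rank-based camera, and the median over list members. Lists without the genes another list holds were added after seeing the data.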

Results

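The comparison asks which transcripts of mouse hepatic macrophages differ when recombinant CPS1 is given before an acetaminophen overdose, a drug injury that kills hepatocytes. CPS1 (carbamoyl phosphate synthetase 1) is a mitochondrial urea cycle enzyme that hepatocytes hold in large amounts. Mice given recombinant CPS1 (rCPS1) were set against mice given recombinant transferrin (rTF), the iron carrier of plasma. The proteins were injected into the tail vein 12 h before 350 mg/kg acetaminophen, at 50 µg for rCPS1 and 25 µg for rTF, so the protein and its amount changed together. Each group held 4 arrays, 8 in all, from male FVB/N mice aged 8 weeks. Every sample title reads Mouse1, followed by the protein and a replicate number. The labels therefore do not settle whether the 4 replicates of a group came from separate mice. The p-values measure only the spread between these samples, which may be technical. The log2 median of an array lay between 3.55 and 3.68. Pairs of arrays correlated at r = 0.967 to 0.983 across array rows, which are not independent replicates, with a mean r of 0.976 both within and between groups. On the first principal component, which held 22.9% of the variance, rTF replicate 2 lay at 42.6 and the other arrays between -23.1 and 7.04. The number of arrays limits the precision, and the median standard error of a gene's log2 difference was 0.15.

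Genes of infiltrating monocytes and of the macrophages they form were lower after rCPS1. The mean log2 level of the 23 measured genes of this list was 8.24 ± 0.017 (SD, n = 4) with rTF and 7.87 ± 0.067 (SD, n = 4) with rCPS1, a difference of -0.37, and each rCPS1 array lay below every rTF array. F13a1 (probe set 17291881), the A subunit of coagulation factor XIII, averaged 8.14 ± 0.46 with rTF and 6.97 ± 0.34 with rCPS1, a log2 difference of -1.17 ± 0.24 (SE). Chil3 (probe set 17408897), a chitinase-like protein of myeloid cells, went from 9.81 ± 0.42 to 8.68 ± 0.31, a difference of -1.13 ± 0.22. Ccr1 (probe set 17532569), a chemokine receptor, differed by -0.95 ± 0.22, and Ly6c2 (probe set 17318100), part of the surface antigen of classical monocytes, by -0.55 ± 0.13. Ccr2, the receptor that draws monocytes out of the bone marrow, differed by -0.51 ± 0.21. Of the 23 members, 20 were lower and 3 higher, 11 had an unadjusted p under 0.05, all lower, and 8 passed when adjusted over the list alone, against 0 over all genes tested. The list fell in the camera test (adjusted p = 8.51e-10, and adjusted p = 0.0106 with an estimated correlation), and the exact permutation test of its mean gave p = 0.0286, the smallest that 4 against 4 allows, or 0.286 after adjustment over the 30 lists. The correlation estimated for this list was -0.028, against 0.19 for the neutrophil list, so that setting made no allowance for correlation between its genes. The estimate rests on 6 residual degrees of freedom and is uncertain. Further members, chosen after their values were seen, were Fn1 (fibronectin, -0.72 ± 0.22), S100a6 (-0.53 ± 0.13) and Lyz2 (lysozyme, -0.32 ± 0.11). The 3 higher members were Ace (0.52 ± 0.29), Cx3cr1 (0.20 ± 0.20) and Spn (0.10 ± 0.14), which patrolling monocytes express, and none of them had an unadjusted p under 0.05. Taken as the median level over members in each array, the group difference was -0.73, whereas the median of the members' own log2 differences was -0.32. Chil3, Ly6c2 and Lyz2 have near-identical relatives whose transcripts the array may not separate, so their values are uncertain.

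Neutrophil genes were lower after rCPS1 as well. The mean log2 level of the 25 measured genes was 5.36 ± 0.23 (SD, n = 4) with rTF and 4.77 ± 0.22 (SD, n = 4) with rCPS1, a difference of -0.60 (1.51-fold lower), with each rCPS1 array below every rTF array. Cxcr2, the receptor that guides neutrophils towards CXC chemokines, averaged 6.99 ± 0.40 with rTF and 5.47 ± 0.80 with rCPS1, a difference of -1.52 ± 0.36 (SE). S100a9, a subunit of calprotectin, differed by -1.13 ± 0.26, Il1r2, the decoy receptor for interleukin 1, by -0.76 ± 0.18, and Csf3r, the receptor for G-CSF, by -0.52 ± 0.13. Members chosen after their values were seen included the granule genes Ngp (-1.72 ± 0.56) and Mmp8 (-1.47 ± 0.36) and the secreted factor Retnlg (-1.54 ± 0.47). Lcn2, which the iron list also holds, differed by -0.96 ± 0.32. Of the 25 members, 22 were lower and 3 higher, and 12 passed when adjusted over the list alone, all lower, against 0 over all genes tested. Only 15 of the 25 lay above the median level of all array rows, and 14 of those 15 were lower. The camera test gave adjusted p = 3.88e-12 for a fall, but adjusted p = 0.199 with an estimated correlation. That setting also uses fewer degrees of freedom, so the lost call cannot be put down to correlation alone. The exact permutation test of the list mean gave p = 0.0286, or 0.286 after adjustment over the 30 lists, and without rCPS1 replicate 4 the difference was -0.50 with an exact p of 0.0571. The median level over members in each array gave a group difference of -1.40, whereas the median of the members' own log2 differences was -0.39.

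**Figure D1:**
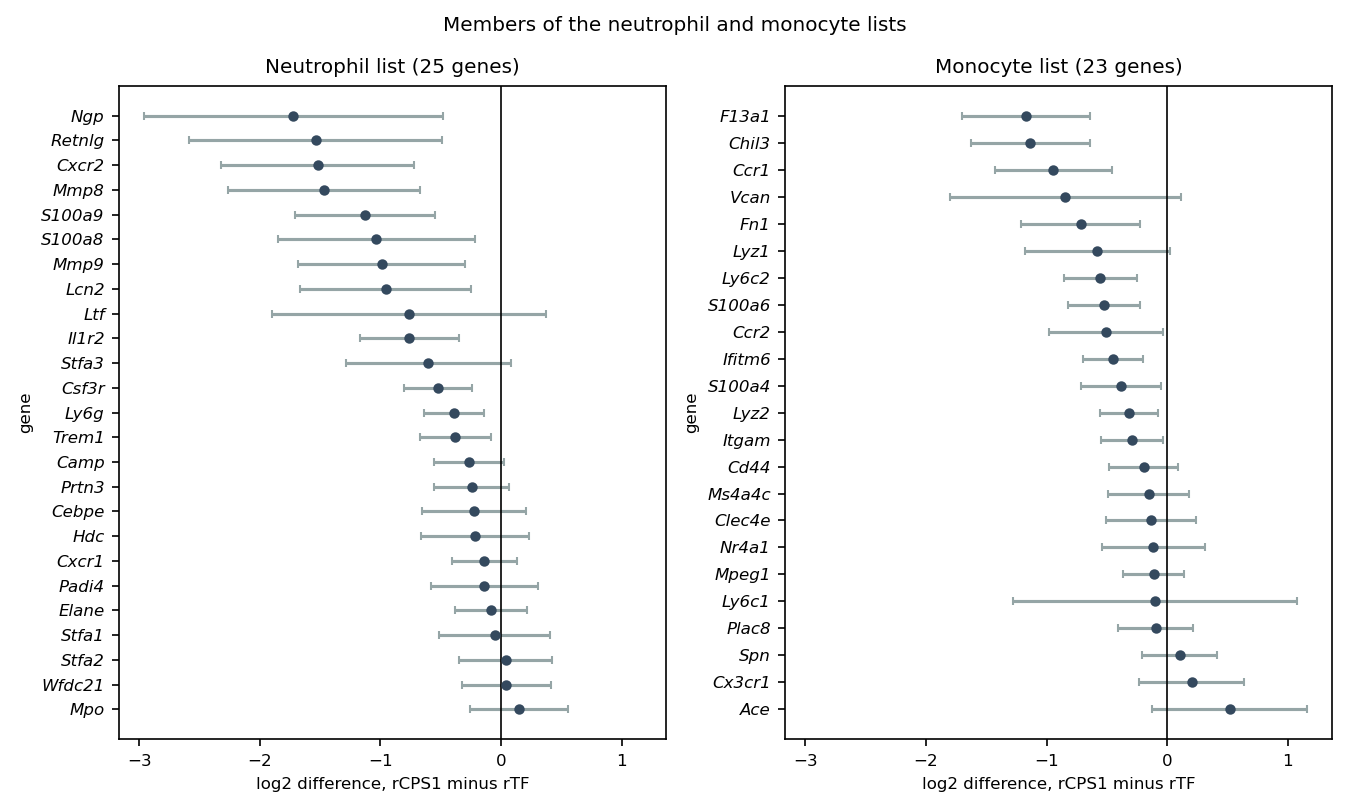
Log2 difference (rCPS1 minus rTF, x axis) of each measured member of the neutrophil list (25 genes) and the monocyte list (23 genes), as points with 95% intervals from the limma fit. In the neutrophil list 22 members and in the monocyte list 20 members lie below 0.

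Chemokines and their receptors on myeloid cells were lower with rCPS1, in part through genes of the lists above: 3 of the 26 measured members also belong to the monocyte list and 1 to the neutrophil list. The list mean was 7.74 ± 0.048 (SD, n = 4) with rTF and 7.49 ± 0.20 (SD, n = 4) with rCPS1, a difference of -0.25, with 21 members lower and 5 higher. Beside Ccr1 and Cxcr2, the chemokine Ccl9 differed by -0.44 ± 0.10 (SE) and the T cell attractant Ccl5 by -0.32 ± 0.11. Ccl5 also belongs to the T and NK cell list and to the classically activated list, so its value is not particular to myeloid cells. In this list 3 members passed when adjusted over the list alone. The camera test gave adjusted p = 0.0008 for a fall, but adjusted p = 0.398 with an estimated correlation, and the exact permutation p of the mean was 0.0571. Genes of tissue repair and lipid-associated macrophages went from 8.06 ± 0.011 to 7.87 ± 0.13 (SD, n = 4 each), a difference of -0.19, with 17 of 25 members lower and 8 higher. Thbs1 (thrombospondin 1) differed by -1.19 ± 0.28, Trem2, a lipid-sensing receptor of macrophages, by -0.57 ± 0.14, the metalloprotease Adam8 by -0.52 ± 0.19 and the integrin Itgax by -0.39 ± 0.13. Of these members 2 passed when adjusted over the list alone. This list fell in the camera test (adjusted p = 0.00799), but gave adjusted p = 0.543 with an estimated correlation, and the exact permutation p of its mean was 0.0286, or 0.286 after adjustment over the 30 lists. Taken as the median level over members in each array, the difference was -0.22 with an exact permutation p of 0.286. The median of the members' own log2 differences was -0.11. Without rCPS1 replicate 4 its camera adjusted p was 0.21 and its mean difference -0.12.

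T and NK cell genes were lower with rCPS1 and type I interferon response genes were higher, both with a large share from rTF replicate 2. The T and NK cell mean was 6.65 ± 0.49 (SD, n = 4) with rTF and 6.24 ± 0.26 with rCPS1, a difference of -0.41, with 20 of 21 members lower, among them the interleukin 7 receptor gene Il7r (-0.49 ± 0.20, SE), the granule protein gene Nkg7 (-0.51 ± 0.22) and Cd5 (-0.77 ± 0.33). None passed when adjusted over the list alone, the exact permutation p of the mean was 0.171, and the camera call of a fall (adjusted p = 1.26e-06) gave adjusted p = 0.759 with an estimated correlation. In rTF replicate 2 this mean was 7.36, against 6.26 to 6.56 in the other rTF arrays, and without that array the difference was -0.17 with a camera adjusted p of 0.00871. Interferon response genes averaged 8.02 ± 0.30 with rTF and 8.20 ± 0.21 with rCPS1, a difference of 0.18, and 22 of 26 members were higher, among them the antiviral GTPase gene Mx2 (0.55 ± 0.26) and the RNA sensor gene Ifih1 (0.47 ± 0.26). No interferon gene passed when adjusted over the list alone, the exact permutation p was 0.40, and the camera call of a rise (adjusted p = 0.00078) gave adjusted p = 0.759 with an estimated correlation. The interferon mean was 7.60 in rTF replicate 2 and 8.08 to 8.32 in the other rTF arrays, and without that array the camera adjusted p was 0.301 and the difference 0.042. The interferon difference was 0.28 without rTF replicate 4, 0.27 without rCPS1 replicate 2 and 0.11 without rCPS1 replicate 4.

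Genes of resident Kupffer cells and NRF2-driven antioxidant genes were slightly higher with rCPS1. The Kupffer cell mean was 8.80 ± 0.20 (SD, n = 4) with rTF and 8.93 ± 0.27 with rCPS1, a difference of 0.13, and 19 of 22 members were higher, among them the scavenger receptor gene Marco (0.41 ± 0.21, SE) and the macrophage surface receptor gene Adgre1 (0.23 ± 0.21). NRF2-driven genes averaged 8.52 ± 0.39 and 8.68 ± 0.25, a difference of 0.15, with 16 of 17 members higher, such as the quinone reductase gene Nqo1 (0.35 ± 0.25) and the thioredoxin reductase gene Txnrd1 (0.27 ± 0.26). No member of these lists passed when adjusted over the list alone, and the exact permutation p was 0.429 for the Kupffer cell mean and 0.60 for the NRF2 mean. Both lists rose in the camera test (adjusted p = 0.0191 each), with adjusted p = 0.759 for each with an estimated correlation. The Kupffer cell call was lost without rTF replicate 2 (adjusted p = 0.121), rTF replicate 3 (0.247), rCPS1 replicate 1 (0.178) or rCPS1 replicate 3 (0.622), and the NRF2 call without rTF replicate 2 (0.633), rTF replicate 4 (0.173), rCPS1 replicate 2 (0.322) or rCPS1 replicate 3 (0.0996). With 1 array left out the Kupffer cell difference ran from 0.025 (without rCPS1 replicate 3) to 0.21 (without rTF replicate 1), and the NRF2 difference from 0.014 (without rTF replicate 2) to 0.32 (without rTF replicate 1).

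**Figure D2:**
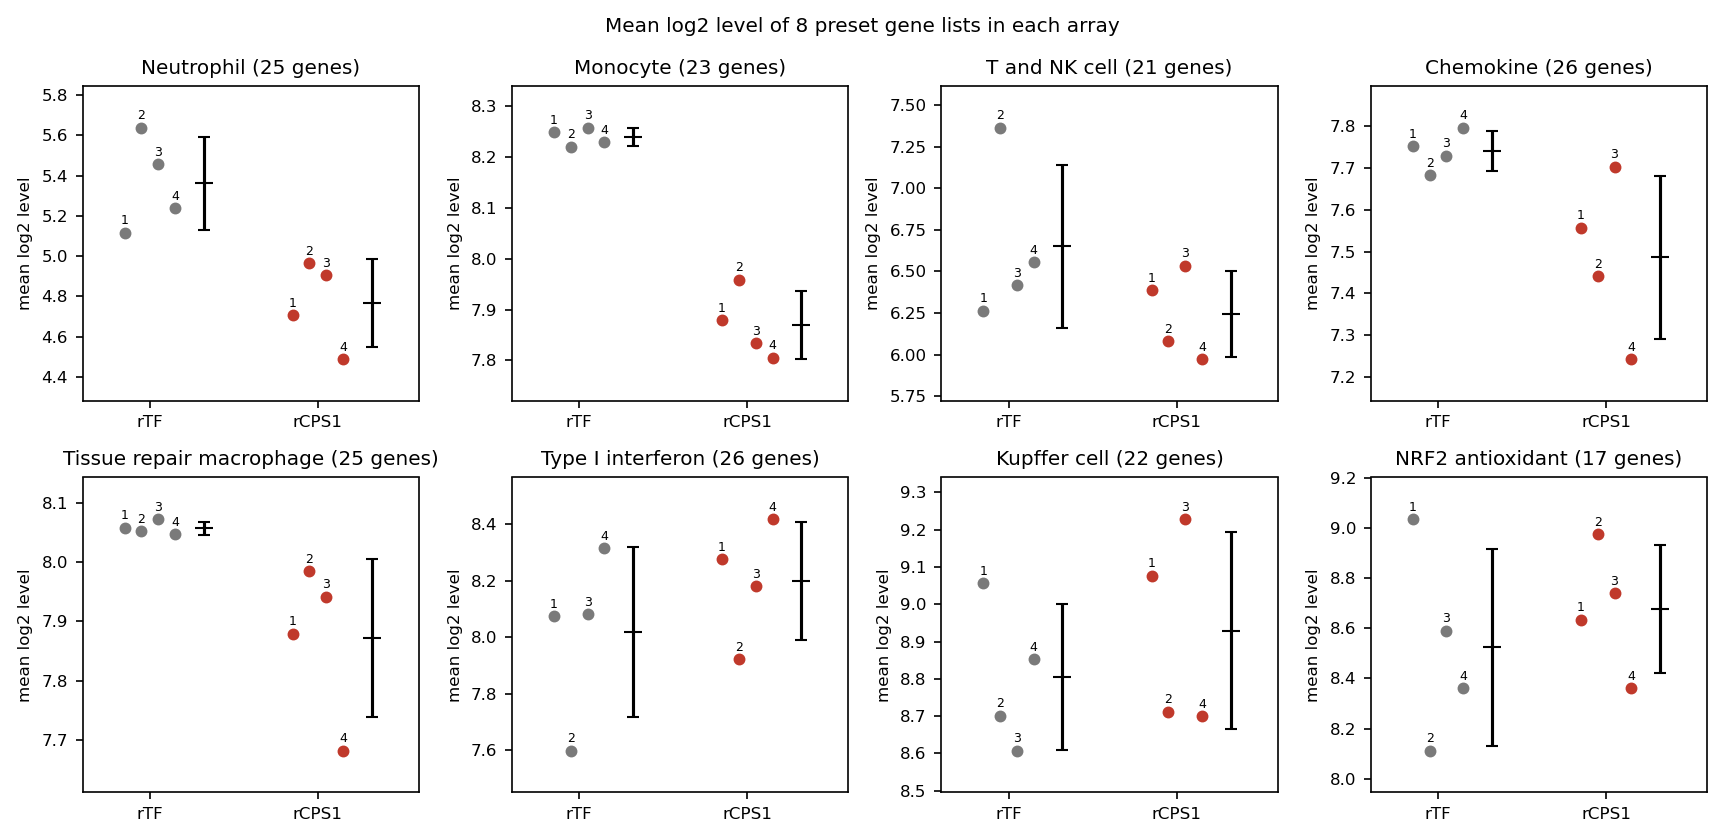
Mean log2 level (y axis, scaled separately for each list) of the 8 preset gene lists past the camera threshold, with points for single arrays numbered by replicate (gray rTF, red rCPS1) and bars for the mean ± SD of 4 arrays. In the neutrophil, monocyte and tissue repair plots all 4 rCPS1 arrays lie below all 4 rTF arrays, and rTF replicate 2 stands apart in the T and NK cell plot (7.36) and the interferon plot (7.60).

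Markers of macrophage activation did not pass in either direction. Classically activated (inflammatory) genes differed by -0.078 in the mean (14 of 23 lower, camera adjusted p = 0.243), and alternatively activated genes by -0.14 (16 of 26 lower, camera adjusted p = 0.0729), where Chil3 alone passed when adjusted over the list alone. The inflammatory enzyme and cytokine genes Nos2 (0.01 ± 0.19, SE), Tnf (-0.022 ± 0.22), Il1b (-0.19 ± 0.14) and Il6 (-0.26 ± 0.28) did not pass, and neither did Arg1 (0.048 ± 0.34), the mannose receptor gene Mrc1 (0.066 ± 0.12), Retnla (-0.15 ± 0.51), Cd163 (0.11 ± 0.39) and Il10 (-0.12 ± 0.26). The monocyte attractant gene Ccl2 differed by -0.092 ± 0.20, and the Kupffer cell genes Clec4f and Timd4 by 0.17 ± 0.24 and 0.11 ± 0.16. For the injected proteins, Cps1 mRNA differed by 0.36 ± 0.24 and the transferrin receptor gene Tfrc by 0.30 ± 0.14, and the transferrin gene, present only on an array row shared with another gene, was not analysed here.

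No single gene passed on its own. With limma, 0 of 22180 genes had an adjusted p under 0.05 (smallest 0.862), and 1035 had an unadjusted p under 0.05, 416 higher and 619 lower with rCPS1, against 1109 expected with no effect. The groups did not overlap for 648 genes (2.92%), against 2.86% by chance. The 12 lower genes of smallest p included 4 from the preset lists, Chil3, F13a1, Ccr1 and S100a9. Others among them were Ly6a2 (-0.78 ± 0.17, SE), the semaphorin gene Sema7a (-0.68 ± 0.15), the growth factor gene Nrg1 (-0.79 ± 0.18), Sirpb1a (-0.55 ± 0.12), the chitinase-like gene Chil1 (-0.56 ± 0.12) and Slc13a3, a dicarboxylate transporter gene (-0.67 ± 0.13). The 12 higher genes of smallest p had log2 differences of 0.60 to 0.87 and none was in a preset list. They included Cdkl3 (0.85 ± 0.16), Efcab12 (0.87 ± 0.17), Abca4, a retinoid transporter gene (0.80 ± 0.16), Coq3, an enzyme gene of ubiquinone synthesis (0.60 ± 0.11), and BC023105 (0.67 ± 0.16). All of these genes had an adjusted p of 0.862.

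Other liver cell types and pathways did not pass the camera test. Hepatocyte genes averaged 7.23 ± 0.21 (SD, n = 4) with rTF and 7.24 ± 0.29 with rCPS1 (difference 0.016, adjusted p = 0.719). Sinusoidal endothelial genes averaged 10.89 ± 0.16 and 10.89 ± 0.13, a difference of 0.0054 (adjusted p = 0.534). That level was above the Kupffer cell mean (8.80 with rTF and 8.93 with rCPS1), so the preparation may have held endothelial cells beside macrophages. Array levels of different genes do not give cell shares. Stellate cell and fibroblast genes differed by -0.15 (14 of 20 lower, adjusted p = 0.243), dendritic cell genes by -0.16 (13 of 18 lower, 0.0666), B cell genes by 0.087 (13 of 16 higher, 0.243), red cell precursor genes by -0.096 (0.541) and bile duct genes by -0.015 (0.819). Among signalling lists, NF-kappaB targets differed by -0.085 (19 of 21 lower, 0.173), immediate early genes by -0.10 (18 of 24 lower, 0.232) and unfolded protein response genes by -0.11 (17 of 23 lower, 0.126). Class II antigen presentation genes differed by -0.081 (0.243), cell cycle genes by -0.076 (0.590), lysosomal genes by -0.038 (0.399), complement genes by -0.0074 (0.859) and uptake receptors for dying cells by -0.0014 (0.590). Among metabolic lists, urea cycle and arginine genes differed by 0.067 (0.316), with Arg2 at -0.47 ± 0.20 (SE), and glycolysis genes by 0.0039 (0.859), with Hk1 at 0.49 ± 0.18. Iron and heme genes differed by -0.020 (0.819), LXR-driven lipid genes by 0.018 (0.590) and cholesterol synthesis genes by -0.053 (0.600). The sign of the mean, the median or the camera test differed for the bile duct, iron, glycolysis, complement and uptake receptor lists. Leaving out 1 array brought several of these lists past the threshold: without rTF replicate 1 the dendritic (0.000689), stellate (0.00105), immediate early (0.000503), unfolded protein (0.00185) and alternatively activated (0.0235) lists, without rTF replicate 2 the NF-kappaB (0.00197), classically activated (0.0234), B cell (0.0489) and cell cycle (0.0409, turned to higher) lists. The same happened without rTF replicate 4 for B cells (0.0484), without rCPS1 replicate 1 for dendritic cells (0.0145), without rCPS1 replicate 2 for B cells (4.92e-05) and stellate cells (0.010), without rCPS1 replicate 3 for alternatively activated genes (0.0247), and without rCPS1 replicate 4 for hepatocytes (0.0211) and the urea cycle (0.0481).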

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

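The tests in this part that leave out rTF replicate 2 to weigh that array were chosen after the results were seen. In each group of 4 arrays, the highest or lowest array was set against the others by Dixon's ratio. It stood apart in 17 of 262 groups of values tested, against 13.1 expected by chance at 1 in 20, and 6 of the 17 were in rTF replicate 2.

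In rTF replicate 2, Nkg7 was at 8.23 (log2, the other rTF arrays 7.26 to 7.32), Ifih1 at 8.48 (9.51 to 9.69), the lysosomal pump gene Atp6v1h at 7.51 (8.22 to 8.33), the red cell gene Epb42 at 4.08 (3.31 to 3.43), the sterol gene Mvd at 5.56 (5.20 to 5.22) and Coq3 at 4.59 (4.83 to 4.87). In the other rTF arrays, the B cell factor gene Ebf1 was at 4.55 in replicate 1 (others 5.61 to 5.76) and the integrin gene Itgam at 9.33 in replicate 3 (9.15 to 9.18). In rTF replicate 4, Cdkl3 was at 3.73 (3.19 to 3.27) and Fam186b at 3.65 (3.15 to 3.20). In rCPS1 replicate 2, the mitotic gene Bub1b was at 3.94 (4.65 to 4.76), the lipid droplet gene Plin2 at 9.95 (9.45 to 9.53) and Nos2 at 4.34 (4.87 to 4.94). In rCPS1 replicate 4, Ccl5 was at 9.89 (9.82 to 9.83) and Nfkbie at 8.86 (8.76 to 8.77). Jund was at 8.64 in rCPS1 replicate 3 (9.41 to 9.54), and the mean of the red cell precursor list was 3.51 in rCPS1 replicate 1 (3.35 to 3.37).

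The array rTF replicate 2 held high T and NK cell genes and low interferon and NRF2 genes, and it may by itself account for some group differences. Without it the interferon list had an adjusted p of 0.301 and the NRF2 list of 0.633, so neither call of a rise held without it, and the NRF2 call held in only 4 of the 8 fits with 1 array left out. The T and NK cell list still passed at the preset correlation without it (adjusted p = 0.00871), but the difference shrank from -0.41 to -0.17 (exact permutation p = 0.371), and with all arrays the call was lost with an estimated correlation (adjusted p = 0.759), so this array as the whole source is left open. A preparation with more T and NK cells remains a candidate explanation for this array, and the labels give no batch or purity value that bears on it. B cell genes had a mean of 6.28 in it, as in rTF replicate 4 (6.28), above rTF replicate 1 (5.49) and rTF replicate 3 (5.92).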

How the results depend on the processing

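All alternatives here were set in advance except the lists without shared genes, added after seeing the data. No gene passed in any of the 16 alternatives of the limma test (smallest adjusted p 0.246, without rTF replicate 1). Genes with an unadjusted p under 0.05 numbered 609 among rows above the median level, where fewer genes were tested, and 1879 over all array rows, where more were, against 1035, and 888 to 1240 with 1 array left out. Against 8 lists, 1 passed with an estimated correlation and 1 with fry, 7 to 13 with 1 array left out (13 without rTF replicate 1), and 7 without shared genes, which ended the Kupffer cell call (adjusted p = 0.182). The monocyte list passed in all 17 alternatives, with adjusted p from 3.17e-10 to 0.0106. Over the alternatives, 463 list tests kept their side of the threshold, 25 lost a call, 19 gained one and 1 turned, the cell cycle list without rTF replicate 2 (adjusted p = 0.0409, and 0.0409 to 0.924 with 1 array left out). Dendritic cell genes passed above the median level (0.0438), with quantile normalization (0.0429) and with the mean of all rows (0.0285), and alternatively activated genes above the median level (0.0237). The cause was not tested. The tissue repair mean difference was -0.22 as a median over members (exact permutation p = 0.286) and -0.22 to -0.12 with 1 array left out, the neutrophil one -0.68 to -0.50 and the monocyte one -0.40 to -0.35. Same-numbered arrays did not deviate together (correlations -0.124 to 0.025, 0 of 8 arrays closest to their own number), so no shared effect of the number was seen. Whether same-numbered samples were handled together is not settled by this. With the replicate block 0 genes passed, 997 had an unadjusted p under 0.05 and the same 8 lists passed. Sign flips within numbers gave the monocyte (-0.37), neutrophil (-0.60) and tissue repair (-0.19) differences an exact p of 0.125, the smallest 4 pairs allow. Of 1505 alternative values of named genes none was called, and 25 changed sign, in 10 genes (Nos2, Tnf, Cd163, Arg1, Retnla, Ccl2, Mrc1, Il6, Il10 and Clec4f). Signal near background limits the neutrophil list most among the 8 that passed, with 10 of 25 genes at or below the median level.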

Other observations

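The 11 lists and all tests on them, the tests against other cell sources, the comparison of monocyte subsets, and the counts of splits for the estimated correlation and for the smallest list p were chosen after the results were seen. The other counts of splits were written down before their results were seen.

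Receptors for cytokines and microbial products on myeloid cells were lower with rCPS1. Of 29 measured genes 23 were lower and 6 higher. Among the 5 lower genes with an unadjusted p under 0.05, 2, Csf3r and Il1r2, belong to the neutrophil list. Of the 29 genes 1 belongs to the monocyte list, so this result is not wholly separate from those lists. The receptor list had a mean difference of -0.17 (exact permutation p = 0.0571). Clec5a, a myeloid receptor that signals through DAP12, differed by -0.82 ± 0.20 (SE), Cd14, the co-receptor for bacterial lipopolysaccharide, by -0.38 ± 0.11, and Il1rap by -0.39 ± 0.15, while Csf1r differed by -0.01. Camera gave adjusted p = 0.00025 for a fall over the 11 lists, and adjusted p = 0.0698 with an estimated correlation. Cytosolic ribosomal protein genes went from 7.21 ± 0.026 to 7.10 ± 0.033 (SD, n = 4 each), a difference of -0.11 (exact permutation p = 0.0286), with 52 of 63 lower, camera adjusted p = 0.000116 and adjusted p = 0.124 with an estimated correlation.

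Lists drawn from the monocyte and neutrophil lists, and so not independent of them, passed at the preset correlation: the 6 classical monocyte genes (camera adjusted p = 9.23e-10, and adjusted p = 0.0175 with an estimated correlation), the 10 monocyte genes with little expression in neutrophils (0.00278, and adjusted p = 0.0616 with an estimated correlation) and the 7 genes largely restricted to neutrophils (mean difference -1.34, 3.38e-11, and adjusted p = 0.0616 with an estimated correlation). The 4 patrolling monocyte genes did not pass (0.212), and neither did the lists that follow. Leukocyte adhesion genes differed by -0.062 (camera adjusted p = 0.368), although Cd177, a neutrophil surface protein gene, was at -0.93 ± 0.27 (SE) and Selplg, the gene of a selectin ligand, at -0.36 ± 0.16. Platelet genes differed by -0.020 (0.871), eosinophil, basophil and mast cell genes by -0.088 (0.812), proteasome genes by -0.0079 (0.970) and respiratory chain genes by -0.042 (0.289).

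Of the 35 ways to split the 8 arrays into 4 and 4, 17 gave as many genes with an unadjusted p under 0.05 as the real split (1035, highest other 1804). All 35 necessarily gave as many genes past the adjusted threshold, since the real count was 0 (highest other 1), which says nothing about chance. As many lists passed at the preset correlation in 26 of the 35 (8, highest other 17), and in 6 of the 35 some list had a p as small as the smallest here (1.29e-13, smallest other 8.78e-18), so chance is not excluded for the unadjusted genes, for the number of lists or for the smallest list p. With an estimated correlation 1 of the 35, the real split, called as many lists (1, highest other 0). That is the smallest share that 35 splits allow, rests on 1 list in a test chosen after its result was seen, and covers chance among these arrays and not among mice, so chance is not firmly excluded. The monocyte list's exact p was 0.286 after adjustment over the lists.

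The fall of monocyte genes may reflect fewer infiltrating monocytes in the preparation or less of these transcripts in each cell, a hypothesis these arrays leave open. Of the 35 splits 1, the real one, gave this list a p as small (5.67e-11, smallest other 0.000262), which excludes chance among these arrays at 0.05 for this list by itself, not for a list singled out of 30. The 10 members with little expression in neutrophils differed by -0.32 (exact permutation p = 0.0286), which argues against neutrophil RNA as the whole source. However, 3 of the 10 were higher and the camera call was lost (adjusted p = 0.0616 with an estimated correlation). The list without F13a1 and Fn1, which platelets also carry, differed by -0.32 (exact permutation p = 0.0286), so these genes were not its whole source. Platelet genes themselves differed by -0.020 (7 of 14 lower, 7 higher, exact permutation p = 0.886), so no fall of platelet genes was seen. A larger share of other liver cells would lower Kupffer cell genes alike, and these were not lower, with a difference of 0.13 (19 of 22 higher). That rise was small against the spread (exact permutation p = 0.429, and a difference of 0.025 without rCPS1 replicate 3). Hepatocyte genes differed by 0.016 and endothelial genes by 0.0054, so neither list showed a larger share, though these values are too weak to decide. The explanation is still left open, as are the protein given and its amount, because 3 references were tried in turn with the results known and they did not give 1 answer: the difference was -0.28 relative to 5 lists of other cell types (exact permutation p = 0.0857), -0.49 relative to the Kupffer cell list (0.0571) and -0.37 relative to the uptake receptor list (0.0286).

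A hypothesis formed on these data is that classical monocyte genes fell more than patrolling monocyte genes. The 6 classical genes (Chil3, F13a1, Ly6c2, Fn1, Ccr2 and Vcan) differed by -0.82 and the 4 patrolling genes (Ace, Cx3cr1, Spn and Nr4a1) by 0.18, and the difference of the 2 means was -0.999 (exact permutation p = 0.0286, the smallest possible). All 10 genes come from the list already seen to be lower, and the patrolling set holds all 3 of its higher members. The sets were formed with these values known, so the difference and its p do not test the hypothesis.

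The fall of neutrophil genes may come from fewer neutrophils in the preparation. The 7 genes largely restricted to neutrophils, picked after their values were seen, differed by -1.72 to -0.99, and 0 of their 95% intervals left out their median, which does not decide between fewer cells and less of these transcripts in each cell. For a larger share of other liver cells the Kupffer cell, hepatocyte and endothelial values above apply here too, with the same limits. Relative to the same 3 references, in the same order, the difference was -0.51 (exact permutation p = 0.0286), -0.72 (0.0571) and -0.59 (0.0286). A larger share of other liver cells is left open for the same reason. Of the 35 splits 1, the real one, gave this list a p as small (1.29e-13, smallest other 7.48e-10), which excludes chance among these arrays at 0.05 for this list by itself, not for a list singled out of 30, and the adjusted p of 0.199 with an estimated correlation did not pass. A difference in isolation between the groups was not tested and stays open.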
